A study of Mus musculus with 21 samples.

How the data were processed

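The libraries were made from HSC and MEP sorted by flow cytometry from mouse bone marrow, with NucleoSpin RNA XS for extraction and the SMART-Seq v4 Ultra Low Input kit for library preparation, per the labels. The labelled Etv6 genotypes were WT, P216L, S211I and both changes together. Sample titles write S211I where the genotype field writes P211I; the title form is used here. Replicate numbers come from the titles, and MEP WT holds replicates 1 and 3. The labels do not say whether each library came from a separate animal, so p values measure the spread between samples.

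The deposited table holds estimated counts per Entrez gene, which the authors made from the reads; their processing notes name FastQC, Salmon and the assembly GRCm39, and the versions are not given in the sources used here. Between 6.09 and 33.07% of the nonzero values per library are not whole numbers, with up to 3 decimals. They were rounded to whole numbers for the tests. The table holds 30519 genes, of which 30211 took a symbol from an annotation of GRCm38.p6; the other 308 held 0.044% of the counts. The annotation served for names and for the order of neighbouring genes. No read was realigned, and 0 per-sample columns were left out.

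Median counts per library were 480419 in HSC and 6202517 in MEP. By group, HSC WT held 151216 to 480419 counts, HSC P216L 406024 to 850136, HSC S211I 442014 to 13154016, the HSC double mutant 369439 to 2250654, and the MEP groups 3387389 to 12130358. Libraries of a group were checked for duplicates by a chi-square per degree of freedom between their counts, which was 4.79 to 92.6 over 18 pairs, where copies of one library would give 1 or less.

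HSC and MEP were fitted apart with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): trimmed mean of M values (TMM) size factors, filterByExpr with a minimum count of 10 and a minimum total of 15, quasi-likelihood fits with robust estimation, and Benjamini-Hochberg adjustment within each contrast at 0.05. The HSC, MEP and joint fits tested 9471, 10773 and 12036 genes, and the joint fit had a biological coefficient of variation of 1.06. It was 1.60 in HSC and 0.174 in MEP. The joint fit gives each gene 1 spread for both cell types, so its p values do not measure the HSC spread by itself. There were 16 contrasts: each mutant against WT, the double mutant against each single mutant and against the sum of the single-mutant changes in each cell type, MEP against HSC in WT, and the difference of each mutant's effect between cell types. The contrasts across cell types came from the joint fit, so their CPM values for the same group differ slightly from those of the fit of 1 cell type; plain CPM values use the library totals alone. SE values are the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Where every library of a group was at 0, the fold is a lower bound that gives that group 3 counts over its summed libraries. That bound leaves out the spread between libraries, so the true fold may be lower.

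Gene lists were written before the counts were opened, and 27 of the 29 were tested with camera (limma) at a preset correlation of 0.01 between genes, adjusted over the 27 lists in each of 10 contrasts: hematopoietic stem cell, megakaryocyte, platelet cytoskeleton, erythroid, heme synthesis, neutrophil, monocyte, B lymphoid, T and NK cell, mast cell, endothelial and stromal, interferon, antigen presentation, NF-kB and TNF, immediate early, p53 target, S phase, G2 and mitosis, Myc target, ribosomal protein, oxidative phosphorylation, glycolysis and hypoxia, unfolded protein response, cholesterol, ETS family, Etv6 co-repressor, and nuclear export and import. The other 2, sex-linked and mitochondrially encoded genes, were descriptive; the latter is not analysed here. A member is called positive when its log2 fold change is above 0. Counts of members adjusted over the list alone use Benjamini-Hochberg within that list.

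Alternatives were relative log expression (RLE) size factors, no low-count filter, replicate number as a block, a Y-linked covariate in HSC, voom with quality weights (limma), DESeq2 1.42.0, a fit of only the groups compared, and each library left out in turn. A fit without 1 library of a group of 2 takes the spread from the other groups. For lists they also included a correlation estimated for each list and a rotation test (fry). The Y-linked covariate was used where summed Y-linked CPM differed by more than 8-fold: it ranged from 10.8 to 621 in HSC (57.4-fold) and from 224 to 311 in MEP (1.38-fold). Added after the data were seen were fits without the library labelled HSC S211I replicate 2 in contrasts that do not contain it, fits without the 3 HSC libraries nearest to MEP (that library, double-mutant replicate 3 and P216L replicate 3), and HSC libraries thinned to 151215 counts, where 7252 genes were tested.

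The tests were tried on simulated counts, with 200 genes changed by 2-, 4- and 16-fold. These counts were drawn from a negative binomial with the same mean per gene in all libraries and the fitted dispersions and library sizes. They hold no genotype difference beyond the changes put in and no correlation between genes. In MEP 33 to 49 of 67 genes changed 2-fold were recovered in contrasts of 2 groups, 53 to 60 of 67 changed 4-fold and 56 to 64 of 66 changed 16-fold, with 9 to 17 false calls per contrast. In HSC 0 or 1 of 67 was recovered at 2- and 4-fold. A list shifted 1.5-fold passed camera in 5 of 5 MEP contrasts and 0 of 5 HSC contrasts, and 1 list that was not shifted also passed in each of 3 MEP contrasts. Overlaps between contrasts that share libraries were compared with the number under independence and with 20 sets simulated without effects. Correlations between cell types were compared with 100 regroupings of libraries.

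Genes named in the report follow a rule. Etv6 came first, in every library. Against WT, up to 8 genes higher and 8 lower were named that passed the threshold, had a mean of at least 1 CPM and a symbol that is not a placeholder, and had every mutant library on the same side of every WT library; in other contrasts up to 5 per direction. Where fewer than 5 passed in a direction, genes with the smallest p follow as values, up to 5. For lists, up to 4 passing members with the smallest p, or values of 2 members in the list's direction where fewer passed. For MEP against HSC, 1 to 4 members per list are printed in part, and for the interaction contrasts only genes in the direction of the calls. Other genes that complete a count were named after their values were seen. Some genes that the rule selects are not reported here.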

Results

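Hematopoietic stem cells (HSC) and megakaryocyte-erythroid progenitors (MEP) were sorted from the bone marrow of mice carrying wild-type Etv6 (WT), Etv6 P216L, Etv6 S211I or both changes (double mutant). Low-input RNA sequencing gave 21 libraries in 8 groups, with n = 3 libraries per group except HSC S211I, MEP WT and MEP S211I, where n = 2. Of the 11 HSC libraries, 10 held 151216 to 2250654 counts and 3988 to 10275 detected genes. The library labelled HSC S211I replicate 2 held 13154016 counts and 16585 genes. The MEP libraries held 3387389 to 12130358 counts and 12713 to 15889 genes. Variation between libraries of a group was large in HSC (biological coefficient of variation 1.60) and small in MEP (0.174). In counts simulated with the fitted spread, 16-fold changes were put into 66 genes. Of these, 0 to 2 were recovered in the HSC comparisons and 56 to 64 in the MEP comparisons of 2 groups. A missing HSC call therefore carries little information, and values are printed with mean ± SD in CPM (counts per 1e6 normalized counts) or log2 fold change ± SE.

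Etv6 was detected in every library. In HSC its plain CPM was 522, 246 and 200 in WT, 251, 69.2 and 164 in P216L, 258 and 46.5 in S211I, and 381, 409 and 252 in the double mutant. In MEP it was 22.8 and 32.6 in WT, 24.8, 37.6 and 32.2 in P216L, 46.9 and 36.4 in S211I, and 41.8, 29.1 and 31.1 in the double mutant. Etv6 passed the threshold in no mutant comparison: in HSC log2 fold changes from WT were −0.84 ± 1.25 for P216L, −0.82 ± 1.43 for S211I and 0.44 ± 1.25 for the double mutant (edgeR, adjusted p = 0.96, 1 and 1). In MEP they were 0.15 ± 0.24, 0.54 ± 0.26 and 0.26 ± 0.24 (edgeR, adjusted p = 0.99, 0.94 and 1). The MEP P216L value changed sign without P216L replicate 2 (−0.0015), without WT replicate 1 (−0.062) and with voom weights (−0.067). The alleles are amino acid substitutions, so a count per gene does not test the genotype labels.

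Between the WT cell types (n = 2 MEP and 3 HSC), single genes were compared and no list was tested. The carbonic anhydrase genes Car1 and Car2 stood at 10419 ± 311 and 13942 ± 1436.5 CPM in MEP against 469 ± 458 and 2432 ± 1144 in HSC (log2 fold change 4.47 ± 0.91 and 2.52 ± 0.42, edgeR, adjusted p = 0.012 and 0.0017). Rrm1, which encodes a subunit of ribonucleotide reductase, was at 1460 ± 10.3 against 20.4 ± 27.0 CPM (6.12 ± 0.84, adjusted p = 0.0003). Npm1 and Atp5b were higher by 2.78 ± 0.56 and 2.57 ± 0.44. Mmrn1 fell from 1369 ± 630 CPM in HSC to 12.1 ± 9.37 in MEP (−6.82 ± 1.21, edgeR, adjusted p = 0.0023) and Meis1 from 449.7 ± 176 to 5.84 ± 3.30. Procr averaged 171 ± 136 CPM in HSC and was absent from both MEP libraries, at least 1022-fold lower. Hid1, Scarf1 and Nkx2-3 were likewise at 0 in MEP (at least 867-, 753- and 414-fold lower). Golm1, Cldn13, Rfwd3, Atad2 and Mtfr1 were at 0 in HSC and averaged 399.5 ± 20.01, 331 ± 61.9, 331 ± 48.9, 275 ± 23.8 and 261 ± 31.6 CPM in MEP. The ribosomal protein genes Rplp0 (2007 ± 114 against 293 ± 141 CPM) and Rpl4 (2716 ± 129 against 466 ± 125) were higher in MEP. So were Ncl (2502 ± 52.8 against 542.5 ± 137) and Myc (880.4 ± 128 against 143 ± 61.9). Other genes higher in MEP were Mcm2 (981 ± 23.6 against 18.97 ± 32.9), Plk1 (213 ± 21.03 against 0.612 ± 1.06) and Kpna2 (1191.5 ± 161 against 107 ± 105). Higher too were Fth1 (3604.5 ± 233 against 888 ± 274), Gfi1b (585 ± 34.6 against 79.9 ± 35.4) and Tnfaip2 (609 ± 58.7 against 11.2 ± 9.10). Lower in MEP were Cd34 (4.97 ± 4.12 against 437 ± 309), Fli1 (9.05 ± 2.02 against 384 ± 378), Lyz2 (4.06 ± 0.789 against 225 ± 114) and H2-K1 (536 ± 125.5 against 2161 ± 185). Pkm (12.4 ± 14.9 against 912 ± 194) and Arpc1b (65.3 ± 24.2 against 779 ± 124) were lower as well. The immediate early genes Dusp1 (11.7 ± 3.80 against 1215 ± 1139) and Jun (46.04 ± 44.04 against 1622 ± 1376) followed. In all, the contrast WT MEP vs WT HSC had 436 genes higher and 57 lower (edgeR, adjusted p < 0.05). The total of 493 became 266 with the other size factors, 1865 with voom and 2211 with DESeq2, and 0 when only these 2 groups were fitted. It was 222 without HSC WT replicate 2, 135 and 136 without MEP WT replicates 1 and 3, and at most 716.

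Summed CPM of the fixed erythroid list ranged from 5164.5 to 7839 in HSC WT, from 9793 to 44719 in the HSC mutants and from 24395 to 29518 in MEP. The highest, 44719, was HSC P216L replicate 3. Summed CPM of the stem cell list was 5495.5 to 7162.5 in HSC WT, 2401 to 5676.5 in HSC P216L, 2351 to 4921 in the HSC double mutant, 6119.7 in HSC S211I replicate 1 and 724 to 1069.9 in MEP. Against WT that list did not pass camera in P216L or double-mutant HSC (adjusted p = 0.14 and 0.11; 0.72 and 0.76 with an estimated correlation). The library labelled HSC S211I replicate 2 had a stem cell sum of 1402.6 and an erythroid sum of 25067. Its log CPM correlated with the mean of the MEP libraries at r = 0.980, against 0.216 to 0.648 for the other HSC libraries and 0.978 to 0.994 for each MEP library. It was kept under its label. What happens without it is stated below for S211I HSC against WT and for the gene lists. This is not stated for the genes shared by the HSC mutants or the test against the sum of single-mutant changes.

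**Figure D1:**
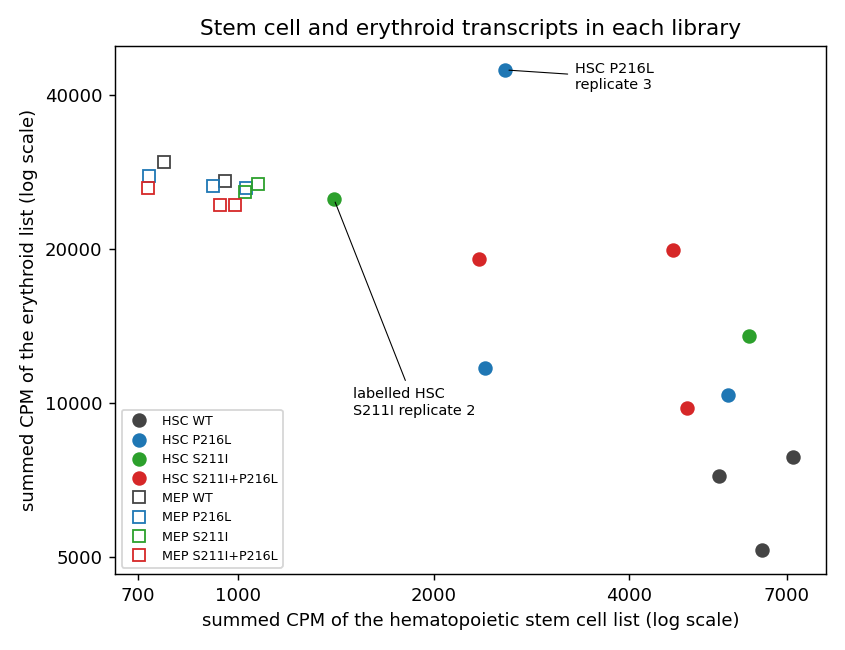
Summed CPM of the stem cell list (x axis, log scale) and of the erythroid list (y axis, log scale) in 21 libraries, filled circles HSC, open squares MEP, coloured by genotype. Each symbol is 1 library; HSC P216L replicate 3 (erythroid sum 44719 CPM) and the library labelled HSC S211I replicate 2 (stem cell sum 1402.6 CPM) are named on the plot.

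In P216L HSC 10 genes passed the threshold against WT, all of them higher (n = 3 and 3). Rrm1 rose from 24.5 ± 32.0 to 945 ± 636 CPM (log2 fold change 5.23 ± 0.88, edgeR, adjusted p = 2.9e-05). Its partner subunit gene Rrm2 rose from 43.0 ± 72.6 to 1414 ± 1245 (5.005 ± 0.98, adjusted p = 0.0028), and the replicative helicase gene Mcm2 from 22.6 ± 39.1 to 917 ± 659 (5.29 ± 1.06, adjusted p = 0.0024). Fech, which encodes the last enzyme of heme synthesis, rose from 227 ± 203 to 1871 ± 1283 CPM (3.03 ± 0.64, adjusted p = 0.0037). The importin gene Kpna2 rose from 129 ± 125 to 1062 ± 652 (3.03 ± 0.68, adjusted p = 0.014). Racgap1, Nde1 and Golm1 had no counts in the 3 WT libraries and averaged 403 ± 367, 375 ± 193 and 304 ± 389 CPM in P216L. That is at least 140.0-, 130.1- and 106-fold higher (edgeR, adjusted p = 0.024, 0.024 and 0.015). The lowest P216L library held Golm1 at 3.83 CPM, less than 3 counts make in a WT library (6.25 to 19.8 CPM). That library cannot be told from WT for Golm1. With H2az1 and Mtfr1 the genes named so far made 10 genes higher and 0 lower (edgeR, adjusted p < 0.05), with 1223 at an unadjusted p under 0.05. Below the threshold, small p values in the other direction belonged to Tsc22d3 (820 ± 360 against 2939 ± 107 CPM, adjusted p = 0.098) and Arap1 (4.74 against 588, adjusted p = 0.12). They also belonged to Cyfip1, Gemin4 and Serpine2, all 3 at 0 in P216L (adjusted p = 0.07, 0.13 and 0.14). Rrm1 passed in 13 of 16 alternative settings and left-out libraries, and the other 7 named genes in 4 to 8. The total was 18 with the other size factors, 60 with voom, 270 with DESeq2 and 0 with only the 2 groups fitted. It was 5 without P216L replicate 3, and 4, 5 and 25 without WT replicates 1, 2 and 3.

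The erythroid list rose in P216L HSC (23 of 26 members positive, camera, adjusted p = 3.2e-07), as did the S phase list (24 of 25, adjusted p = 3.2e-07). Neither passed with an estimated correlation (adjusted p = 0.69 with an estimated correlation). Higher too were heme synthesis (18 of 20, adjusted p = 3.8e-05), G2 and mitosis (21 of 26, adjusted p = 0.00059) and oxidative phosphorylation (27 of 33, adjusted p = 0.011). The immediate early list fell (3 of 16 positive, adjusted p = 0.0064). All 6 calls were lost when camera estimated the correlation within each list (adjusted p = 0.69 to 0.71 with an estimated correlation). Single members past the all-gene threshold numbered 3 in the S phase list and 1 in heme synthesis. Adjusted over the list alone, 7 erythroid, 5 S phase, 3 heme and 2 mitosis members rose. Below the gene threshold, the erythroid factor gene Klf1 stood at 669 ± 189 against 68.1 ± 67.8 CPM (3.28 ± 1.00, adjusted p = 0.20). Atp5b stood at 1585 ± 329 against 698 ± 379 (1.18 ± 0.51, adjusted p = 0.37) and Fos at 169 ± 149 against 932 ± 856 (−2.46 ± 0.93, adjusted p = 0.37). Further values of that kind were Cldn13 at 256 ± 276 CPM and the kinetochore gene Nuf2 at 158 ± 172, both 0 in WT. Tpx2 stood at 237 ± 230.2 against 1.47 ± 1.27, and Fth1 at 2785 ± 1189 against 1088 ± 312. Cox4i1 stood at 461 ± 137 against 95.4 ± 90.4 and Klf6 at 18.7 ± 10.5 against 444 ± 500.3. The mitosis call was lost without P216L replicate 3 (adjusted p = 0.22). The immediate early call was lost without P216L replicates 2 or 3 or WT replicate 1 (0.091, 0.26 and 0.13), and oxidative phosphorylation without P216L replicate 2 or WT replicate 1 (0.051 and 0.063). The mitosis and immediate early calls were also lost without the 3 HSC libraries nearest to MEP (0.27 and 0.24). HSC WT replicate 1 had the highest summed CPM of the immediate early list among WT (17148, WT range 3245 to 17148). The endothelial and stromal sum was 17492 in P216L replicate 1 against 1845 in the highest WT library.

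S211I HSC (n = 2 and 3 WT) showed higher Rrm1 as well, at 1168 ± 558 CPM (5.54 ± 0.92, edgeR, adjusted p = 1.6e-05). The histone variant gene H2az1 rose from 304 ± 88.6 to 2132 ± 1212 CPM (2.81 ± 0.54, adjusted p = 0.00088). Kpna2 rose to 1037 ± 376 (3.00 ± 0.72, adjusted p = 0.039) and Mcm2 to 584 ± 765 (4.64 ± 1.06, adjusted p = 0.028). The Mcm2 rise rests on the library labelled HSC S211I replicate 2: the pair stood at 43.1 and 1124.7 CPM, WT reached 67.8, and without that library the change was 0.84 (adjusted p = 1). C1qtnf12, which encodes a secreted protein, rose from 37.2 ± 38.7 to 794 ± 606 (4.41 ± 1.06, adjusted p = 0.039) and Pacsin2 from 1.46 ± 2.52 to 437 ± 53.7 (7.95 ± 1.88, adjusted p = 0.035). Golm1 and Mtfr1, without counts in WT, averaged 422 ± 73.8 and 399 ± 141 CPM, at least 147- and 139-fold higher (edgeR, adjusted p = 0.02 and 0.0026). These were all 8 genes past the threshold in HSC S211I vs WT, with 0 lower and 772 at an unadjusted p under 0.05. Below it, Anxa1 stood at 17.1 ± 8.07 against 665 ± 191 CPM (adjusted p = 0.17) and Mmrn1 at 298 ± 351 against 1667 ± 727 (adjusted p = 0.20). Tsc22d3 stood at 734 ± 755 against 2939 ± 107 CPM, Wls at 6.10 ± 1.01 against 625 ± 295 and C1ra at 0 against 234 ± 215.8 (edgeR, adjusted p = 0.21, 0.21 and 0.455). Rrm1 passed in 10 of 14 alternatives, H2az1 in 9, Mtfr1 in 8, Golm1 in 7, Mcm2 and C1qtnf12 in 5, and Kpna2 and Pacsin2 in 4. The total was 2 without the library labelled HSC S211I replicate 2, and 4, 4 and 22 without WT replicates 1, 2 and 3. It was 623 with voom, 61 with DESeq2 and 0 with only the 2 groups fitted.

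In S211I HSC 13 lists passed camera. The S phase (25 of 25 positive, adjusted p = 2.9e-05), erythroid (26 of 26, adjusted p = 3.4e-05), G2 and mitosis (22 of 26, adjusted p = 0.00064) and heme synthesis (18 of 20, adjusted p = 0.0018) lists rose (adjusted p = 0.46 with an estimated correlation). The Myc target (22 of 25, adjusted p = 0.0074), oxidative phosphorylation (33 of 33, adjusted p = 0.019) and nuclear export and import (21 of 22, adjusted p = 0.043) lists rose too (adjusted p = 0.46 to 0.56 with an estimated correlation). The stem cell (5 of 24 positive, adjusted p = 0.0017), immediate early (3 of 16, adjusted p = 0.0017) and neutrophil (4 of 14, adjusted p = 0.0017) lists fell (adjusted p = 0.46 with an estimated correlation). So did the megakaryocyte (4 of 19, adjusted p = 0.0025), antigen presentation (5 of 19, adjusted p = 0.01) and platelet cytoskeleton (7 of 17, adjusted p = 0.035) lists. All 13 calls were lost with an estimated correlation (adjusted p = 0.46 to 0.56 with an estimated correlation). In the S phase list 2 members rose and in nuclear transport 1, Kpna2. Adjusted over the list alone, 7 S phase, 4 erythroid, 3 heme, 1 mitosis and 1 transport member rose and 1 megakaryocyte member fell. Leading values below the gene threshold were Klf1 634 ± 336 against 68.1 ± 67.8 CPM, Meis1 114 ± 122 against 549 ± 198 (−2.28 ± 1.33, adjusted p = 0.63), Itgb3 1.89 against 180 CPM and S100a9 6.85 against 163. Cldn13, Uros, Nuf2 and Rrp9 averaged 147, 101, 210.5 and 69.2 CPM and were at 0 in WT. Fech stood at 1012 ± 382 against 227 ± 203 CPM, Tpx2 at 214 ± 27.1 against 1.47 ± 1.27, and Bop1 at 123 ± 104 against 0.738 ± 1.28. Atp5b stood at 1786 ± 1454 against 698 ± 379, Cox4i1 at 442 ± 25.3 against 95.4 ± 90.4 and Nup62 at 360.1 ± 118 against 33.0 ± 55.2. Lower values were those of S100a8 (5.62 against 113 CPM), Robo4 (0.567 against 40.5), Gsn (14.03 against 204), Actn1 (0.236 against 62.2) and H2-M3 (1.61 against 85.2). H2-K1 (1846.5 against 2659), Fos (172 against 932) and Dusp1 (473 against 1538) were among them. Without the library labelled HSC S211I replicate 2, 10 of the 13 calls were lost (adjusted p = 0.063 to 0.91), and the stem cell list turned upward (0.91). That fit keeps 1 S211I library and takes its spread from the other groups, so the 3 calls left do not measure stability. Without WT replicate 1, 5 were lost (0.054 to 0.19), and without WT replicate 2, nuclear transport (0.27). Without the 3 HSC libraries nearest to MEP all 13 were lost (0.087 to 0.92), the stem cell list again turning upward (0.92), and with the other size factors oxidative phosphorylation and nuclear transport were (0.067 for both).

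Double-mutant HSC (n = 3 and 3 WT) had higher Rrm1 (609 ± 288 CPM, 4.60 ± 0.86, edgeR, adjusted p = 0.00077) and H2az1 (1845 ± 799, 2.60 ± 0.51, adjusted p = 0.0013). Kpna2 (1300 ± 959, 3.32 ± 0.69, adjusted p = 0.0043) and Pacsin2 (343 ± 279, 7.61 ± 1.82, adjusted p = 0.039) were higher too. Mtfr1 averaged 360 ± 420 CPM, at least 125-fold above WT (adjusted p = 0.0024). The stromal chemokine gene Cxcl12 and the secreted peroxidase gene Gpx3 had no counts in the 3 double-mutant libraries against 502 ± 590 and 272 ± 417 CPM in WT. They were at least 699- and 379-fold lower (edgeR, adjusted p = 0.037 and 0.011), and each was also at 0 in 1 WT library. That gave 5 genes higher and 2 lower, with 997 at an unadjusted p under 0.05. Below the threshold, Rhag stood at 550 ± 283 against 75.1 ± 61.3 CPM (2.86 ± 0.98, adjusted p = 0.43). Avl9 was at 0 against 163 (adjusted p = 0.083) and Rab27b at 0 against 176 ± 166 (adjusted p = 0.44). Lig3 and Hdac6 were at 0 against 8.02 ± 13.9 and 178 ± 280 CPM (edgeR, adjusted p = 0.34 and 0.375). Rrm1 passed in 12 of 16 alternatives, H2az1 in 11 of 16 and Mtfr1 in 10 of 15. Kpna2 passed in 7 of 16, Cxcl12 and Gpx3 in 6 of 15 each and Pacsin2 in 3 of 15. The total was 1 without double-mutant replicate 3, and 4 and 24 without WT replicates 2 and 3. It was 221 with voom, 128 with DESeq2 and 0 with only the 2 groups fitted.

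The erythroid (26 of 26 positive, camera, adjusted p = 6.9e-07), S phase (24 of 25, adjusted p = 2.6e-05) and heme synthesis (18 of 20, adjusted p = 0.0025) lists rose in double-mutant HSC (adjusted p = 0.67 with an estimated correlation). So did the G2 and mitosis (21 of 26, adjusted p = 0.0074), Myc target (21 of 25, adjusted p = 0.012) and oxidative phosphorylation (32 of 33, adjusted p = 0.02) lists. The megakaryocyte (6 of 19 positive, adjusted p = 0.0014) and immediate early (5 of 16, adjusted p = 0.037) lists fell. All 8 calls were lost with an estimated correlation (adjusted p = 0.67 with an estimated correlation). Of single members of these lists only Rrm1 passed. Adjusted over the list alone, 9 erythroid, 4 heme and 3 S phase members rose. Below the gene threshold Mcm2 stood at 387 ± 419 against 22.6 ± 39.1 CPM (4.04 ± 1.00, edgeR, adjusted p = 0.063). Cldn13, Uros, Nuf2 and Rrp9 averaged 227, 169, 111 and 142 CPM and were at 0 in WT. Fech stood at 742 ± 436 against 227 ± 203, and Plk1 at 142 ± 40.7 against 0.729 ± 1.26. Bop1 stood at 166 ± 85.9 against 0.738 ± 1.28, Atp5b at 1524 ± 242 against 698 ± 379 and Ndufv1 at 348.5 ± 192 against 44.2 ± 34.4. Pf4 and Hspa1b were at 0 against 15.5 ± 26.8 and 64.3 ± 81.0 CPM, and Klf6 was at 76.7 ± 89.95 against 444 ± 500.3. The endothelial and stromal list stayed below the threshold (adjusted p = 0.079), with direction down although 8 of 13 members were positive. Double-mutant replicate 3 had the highest summed CPM of that list in its group, 8173.6. Without double-mutant replicate 3, 6 calls were lost and the erythroid and S phase calls remained (adjusted p = 0.071 to 0.84 for those lost). Without WT replicate 1, 3 were lost (0.066 to 0.34), and the immediate early call also without WT replicate 2 (0.11) or the library labelled HSC S211I replicate 2 (0.15). Without the 3 HSC libraries nearest to MEP 4 were lost (0.17 to 0.99).

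H2az1, Kpna2, Mtfr1 and Rrm1 were higher in all 3 mutant HSC groups. Independent calls would share 4.5e-06 genes, and each of 20 sets simulated without effects shared 0. These sets were not matched to the number of real calls, so they do not show how many genes shared libraries alone would give. P216L and S211I shared 6, adding Golm1 and Mcm2 (0.0084 if independent, at most 1 in the simulated sets). The Mcm2 rise in S211I rests on the library labelled HSC S211I replicate 2, which enters every S211I call here. S211I and the double mutant shared 5, adding Pacsin2 (0.0042), and P216L and the double mutant 4 (0.0053). All comparisons used the same 3 WT libraries, so part of each excess may come from those controls. H2az1, Kpna2, Mtfr1 and Rrm1 also stood higher in MEP (mean 2578, 910.5, 224 and 1174.5 plain CPM) than in HSC WT (304, 129, 0 and 24.5 CPM). MEP RNA in the mutant HSC libraries would therefore raise all 4, which was not tested for these genes. The overlap of P216L and the double mutant ranged from 1 to 22 when single libraries were left out. The overlap of all 3 mutants was not rerun in this way. Mtfr1 was at 0 in 1 P216L library and at 4.25 CPM in the lowest double-mutant library.

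Among the HSC mutants, the DNA ligase gene Lig3 had no counts in the double mutant, against 262 ± 188 CPM in S211I (at least 365-fold lower, edgeR, adjusted p = 0.0071, n = 3 and 2). In P216L it averaged 636 ± 1070 CPM (at least 886-fold, adjusted p = 0.0006, n = 3 and 3), where 1 library was at 0. Gpx3 was at 0 against 485 ± 837 CPM in P216L (at least 676-fold lower, adjusted p = 0.0092). For both genes the SD in P216L was near the highest that 3 libraries with such a mean can give. Nearly all of their CPM in P216L therefore lay in 1 library for each gene. No other gene passed: 0 higher and 1 lower against S211I (193 at an unadjusted p under 0.05), 0 higher and 2 lower against P216L (660). Below the threshold, Klrb1c stood at 411 ± 194 CPM against 0 in P216L (adjusted p = 0.25), and S100a9 at 552 ± 549 against 6.85 ± 9.68 in S211I (6.17 ± 1.95, adjusted p = 1). S100a8 (553 ± 438 against 5.62 ± 7.95 CPM), Anxa1 (376 ± 119.7 against 17.1 ± 8.07), and Wls (216.1 ± 131 against 6.10 ± 1.01) also had small p values against S211I. So had Lyz2 (570 ± 233 against 134 ± 112), Cd300a (126 ± 124 against 1.28 ± 1.80) and C4b (296 ± 255.5 against 0), while Avl9, Gm4631 and Plk2 were at 0 against 74.7, 103 and 143 CPM. Against P216L, Cyfip1, Gemin4, Pigg and Vps11 averaged 168, 92.7, 151.5 and 93.0 CPM against 0, and Avl9, Thada and Gm4631 were at 0 against 270.3, 256 and 169. Against S211I the neutrophil list rose (13 of 14 positive, camera, adjusted p = 2.2e-05; 3 members adjusted over the list alone) and the monocyte list rose (8 of 8, adjusted p = 0.0012). Both calls were lost with an estimated correlation (adjusted p = 0.48 and 0.38 with an estimated correlation), and the monocyte call also without the library labelled HSC S211I replicate 2 (0.29) or without the 3 HSC libraries nearest to MEP, where 1 call was lost (0.62). Against P216L 0 lists passed. The Lig3 call against S211I was lost without S211I replicate 1 or any double-mutant library, and both calls against P216L without P216L replicate 1 or double-mutant replicates 1 or 3.

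Double-mutant HSC were tested against the sum of the single-mutant changes on the log2 scale. There 6 genes fell short of the sum and 0 exceeded it (edgeR, adjusted p < 0.05, 796 at an unadjusted p under 0.05). With RLE size factors some genes exceeded the sum, and fewer calls were left without the low-count filter. Rrm1 averaged 24.6, 890.35, 1014.5 and 542 plain CPM in WT, P216L, S211I and the double mutant (−6.17 ± 1.15, adjusted p = 0.00043), and Mcm2 21.5, 861, 474 and 335 (−5.88 ± 1.38, adjusted p = 0.046). For Mcm2 the S211I pair stood at 43.1 and 1124.7 normalized CPM, and WT reached 67.8. The high value is that of the library labelled HSC S211I replicate 2. Golm1, Mtfr1, Lig3 and Wdr44 were the other 4 of the 6 genes. The count ran from below to above 6 when single libraries were left out. Golm1, Mtfr1 and Wdr44 had no counts in WT, where a log2 change is least certain. Mcm2 and Lig3 had none in 2 of the 3 WT libraries. A gene raised alike in all 3 mutants falls short of the sum on this scale, as Mtfr1 did (246, 369 and 316 plain CPM). Falling short therefore does not by itself show that the changes interact. In the other direction the smallest p values were those of Klrb1c, Wls, Gbp4, C4b and Anxa1 (edgeR, adjusted p = 0.068 to 0.171).

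In P216L MEP no gene passed the threshold against WT (n = 3 and 2; edgeR 0, voom 0, DESeq2 2), and 552 genes had an unadjusted p under 0.05. Among higher genes the smallest p values belonged to D3Ertd751e (16.7 ± 3.17 against 4.69 ± 2.62 CPM, 1.75 ± 0.35, edgeR, adjusted p = 0.31) and Spice1 (16.7 ± 2.01 against 6.97 ± 1.66, 1.27 ± 0.30, adjusted p = 0.71). Among lower genes they belonged to Tspan15 (14.6 ± 3.77 against 45.6 ± 17.9, −1.65 ± 0.30, adjusted p = 0.26), Fhdc1 (9.82 against 27.6, adjusted p = 0.40) and Crip2 (109 ± 7.01 against 170 ± 6.68, −0.64 ± 0.14, adjusted p = 0.40). Pim2 (9.12 ± 4.38 against 2.75 ± 0.614 CPM), Akr1c13 (23.6 ± 4.81 against 11.4 ± 1.28), and Ube2d1 (19.1 ± 3.95 against 8.61 ± 3.16) followed among the higher genes. Abat (0.359 ± 0.247 against 4.78 ± 1.497) and Cnn3 (134 ± 24.8 against 196 ± 2.96) followed among the lower. Without WT replicate 3, 7 genes passed. Changes put into simulated counts were recovered for 44 of 67 genes at 2-fold and 55 of 67 at 4-fold.

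Lists that rose in P216L MEP were the interferon (27 of 33 positive, camera, adjusted p = 7.5e-06), neutrophil (13 of 14, adjusted p = 2.8e-05; 1 member adjusted over the list alone) and antigen presentation (14 of 18, adjusted p = 0.012) lists (adjusted p = 0.57 to 0.62 with an estimated correlation). The erythroid (8 of 26 positive, adjusted p = 0.017), G2 and mitosis (6 of 26, adjusted p = 0.017) and p53 target (3 of 17, adjusted p = 0.02) lists fell. All 6 calls were lost with an estimated correlation (adjusted p = 0.57 to 0.62 with an estimated correlation). The shifts were small: Rhag stood at 712 ± 67.2 against 944 ± 127 CPM (−0.41 ± 0.12, edgeR, adjusted p = 0.98) and B2m at 1173 ± 45.5 against 924 ± 193 (0.34 ± 0.13). Irf7 stood at 25.5 ± 13.1 against 14.8 ± 2.20, and Mmp8 at 1.78 ± 1.30 against 0. Psmb9 stood at 61.5 ± 5.51 against 41.8 ± 14.7 CPM, Sp100 at 61.8 ± 10.2 against 43.9 ± 14.7 and S100a9 at 4.47 ± 4.94 against 0.727 ± 0.0262. Bub1 stood at 104 ± 19.4 against 129.5 ± 10.4. Mki67 stood at 215.8 ± 15.4 against 255 ± 0.529, Ccng1 at 223 ± 11.3 against 262 ± 1.80 and Ckap2 at 68.1 ± 11.9 against 85.4 ± 5.42. Only the neutrophil call held without every library in turn. Without P216L replicate 1, 5 calls were lost (adjusted p = 0.055 to 0.082), 4 without WT replicate 1 (0.091 to 0.63, antigen presentation turning in direction) and 2 without P216L replicate 2 (0.081 and 0.095).

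S211I MEP (n = 2 and 2) also had no gene past the threshold (edgeR 0, voom 0, DESeq2 0; 511 at an unadjusted p under 0.05). D3Ertd751e and Spice1 were again among the smallest p values (16.5 ± 0.892 and 17.5 ± 4.27 CPM, 1.75 ± 0.37 and 1.35 ± 0.32, edgeR, adjusted p = 0.94 for both). Gm7334 (6.23 ± 2.25 CPM against 0) and Cenpc1 (67.3 ± 10.3 against 36.3 ± 10.02) followed among the higher genes. Zfp729a (4.56 ± 0.140 against 13.2 ± 2.08), Slc7a8 (0.182 ± 0.00559 against 3.20 ± 1.24), Helb (21.7 ± 1.70 against 37.7 ± 2.99) and Trnp1 (1.10 ± 0.291 against 8.63 ± 1.07) followed among the lower. Recovery of changes put into simulated counts was 35 of 67 at 2-fold and 56 of 67 at 4-fold.

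In S211I MEP the ribosomal protein list fell, with 0 of 51 members positive (camera, adjusted p = 1.2e-13, 0.67 with an estimated correlation). Rpl13 stood at 881 ± 4.17 against 1159 ± 238 CPM (−0.40 ± 0.15) and Rps6 at 733 ± 23.5 against 943 ± 83.9 (−0.36 ± 0.15). Oxidative phosphorylation (1 of 33 positive, adjusted p = 0.00036), erythroid (4 of 26, adjusted p = 0.022) and Myc target (6 of 25, adjusted p = 0.036) lists fell (adjusted p = 0.64 to 0.67 with an estimated correlation). The neutrophil (13 of 14, adjusted p = 0.0034), antigen presentation (14 of 18, adjusted p = 0.0045), stem cell (13 of 15, adjusted p = 0.0045) and interferon (23 of 33, adjusted p = 0.012) lists rose (adjusted p = 0.64 to 0.67 with an estimated correlation). Cd34 stood at 14.9 ± 0.573 against 4.28 ± 3.55 CPM and B2m at 1264 ± 101 against 924 ± 193. Angpt1 stood at 30.99 ± 6.75 against 20.1 ± 9.46 CPM, Gbp7 at 83.1 ± 1.58 against 61.9 ± 10.2, and Oasl2 at 4.42 ± 2.97 against 1.18 ± 0.913. Psmb9 stood at 64.1 ± 0.868 against 41.8 ± 14.7, Csf3r at 2.39 ± 1.36 against 0.290 ± 0.410 and Mmp8 at 0.985 ± 1.13 against 0. Among the lists that fell, Npm1 stood at 1063 ± 47.8 against 1303 ± 91.5, Ddx21 at 224 ± 2.54 against 278 ± 0.915, and Cyc1 at 366 ± 4.74 against 427 ± 19.6. Ndufv2 stood at 299.96 ± 4.04 against 352 ± 2.59, Rhag at 715 ± 9.65 against 944.5 ± 127 and Hba-a2 at 170.5 ± 5.87 against 300.1 ± 95.1. The ribosomal call alone passed in every fit with a library left out; each such fit has a group of 1 library and takes its spread from the other groups. Of the others 6 were lost without WT replicate 1 (0.070 to 0.91), where antigen presentation turned downward (0.91), 4 without S211I replicate 1 (0.054 to 0.33), 5 without S211I replicate 2 (0.15 to 0.69) and Myc targets without WT replicate 3 (0.16). With replicate number as a block, oxidative phosphorylation and interferon were lost (0.17 and 0.066).

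Double-mutant MEP differed from WT in 11 genes (n = 3 and 2). Mbd2, which encodes a methyl-CpG binding protein, fell from 471 ± 19.9 to 199 ± 21.97 CPM (−1.25 ± 0.12, edgeR, adjusted p = 9.1e-06). The cold shock domain gene Ybx3 fell from 1545 ± 56.4 to 836 ± 116 (−0.89 ± 0.11, adjusted p = 0.00078) and the ubiquitin ligase scaffold gene Cul3 from 161 ± 27.3 to 78.2 ± 0.90 (−1.04 ± 0.15, adjusted p = 0.0024). The RNA-binding protein gene Qk fell from 128 ± 7.55 to 64.6 ± 0.91 (−0.99 ± 0.16, adjusted p = 0.010). Cyhr1 (73.9 ± 3.97 to 32.3 ± 7.25), Znrf2 (58.5 ± 13.9 to 27.6 ± 0.60), Ppp2cb (112.5 ± 6.61 to 59.1 ± 7.09) and Smad4 (39.3 ± 7.24 to 18.2 ± 1.18) fell. Their changes were −1.20 ± 0.21, −1.09 ± 0.19, −0.93 ± 0.15 and −1.10 ± 0.21 (edgeR, adjusted p = 0.015, 0.015, 0.012 and 0.035). Cyclin D1 (Ccnd1) rose from 3.11 ± 1.36 to 20.2 ± 5.47 CPM (2.76 ± 0.47, adjusted p = 0.015). Alox5 rose from 2.45 ± 1.22 to 14.3 ± 1.69 (2.46 ± 0.44, adjusted p = 0.022) and Hexa from 25.1 ± 10.7 to 59.9 ± 8.02 (1.23 ± 0.24, adjusted p = 0.040). These 3 higher and 8 lower genes were all that passed, with 565 at an unadjusted p under 0.05. Bex4 (75.5 ± 8.71 against 31.6 ± 14.1 CPM, 1.28 ± 0.26, edgeR, adjusted p = 0.066) and Rps4l (15.6 ± 3.72 against 4.39 ± 2.455, 1.76 ± 0.38, adjusted p = 0.088) came next among the higher genes. Mbd2 and Ybx3 passed in 11 of 11 alternatives, Cul3 in 10, Qk in 9, and the other 7 genes in 6 to 8. The total was 21 with only the 2 groups fitted, 25 with DESeq2, 39 with voom and 40 without the low-count filter. It was 7, 5, 7 and 3 without WT replicate 1, WT replicate 3, double-mutant replicate 1 and double-mutant replicate 2.

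In double-mutant MEP the B lymphoid (0 of 13 positive, camera, adjusted p = 0.00058) and endothelial and stromal (0 of 6, adjusted p = 0.00058) lists fell (adjusted p = 0.67 and 0.22 with an estimated correlation). So did the erythroid (6 of 26, adjusted p = 0.00058), p53 target (3 of 17, adjusted p = 0.0016) and megakaryocyte (7 of 18, adjusted p = 0.002) lists, and the neutrophil list rose (12 of 14, adjusted p = 0.00058). All 6 calls were lost with an estimated correlation (adjusted p = 0.22 to 0.67 with an estimated correlation). No member passed over all genes. Adjusted over the list alone, 3 megakaryocyte, 3 endothelial and 1 neutrophil member did. Values below the threshold were Car2 9661 ± 516 against 12001 ± 1225 CPM (−0.31 ± 0.11, edgeR, adjusted p = 0.69), Plek 3.15 against 9.78 (−1.67 ± 0.44, adjusted p = 0.33) and Cd79a 2.89 against 7.21. Further values were Mmrn1 2.73 ± 1.05 against 10.4 ± 8.06 CPM, Fcrla 0.353 ± 0.196 against 3.07 ± 0.339, and Cxcl12 0.0384 ± 0.0665 against 2.10 ± 1.47. The others were Pdgfrb 2.71 ± 0.892 against 7.48 ± 2.07, Ccng1 217 ± 9.34 against 262 ± 1.80 and Sesn2 7.30 ± 1.13 against 12.8 ± 3.15. In the neutrophil list Elane stood at 4.91 ± 3.50 against 0.166 ± 0.234 and Mmp8 at 1.53 ± 1.34 against 0. Calls were lost without WT replicate 3 for B lymphoid (0.37) and endothelial (0.11), and without WT replicate 1 for erythroid (0.27) and p53 (0.055). They were also lost without double-mutant replicate 1 for p53 (0.056) and without double-mutant replicate 3 for megakaryocyte (0.060).

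Against S211I MEP (n = 3 and 2), the double mutant had 0 genes higher and 15 lower (edgeR, adjusted p < 0.05, 821 at an unadjusted p under 0.05). Qk stood at 64.6 ± 0.91 against 176 ± 8.22 CPM (−1.44 ± 0.16, adjusted p = 7.0e-05). Mbd2 (199 ± 21.97 against 432 ± 23.5), Ybx3 (836 ± 116 against 1483 ± 36.3) and Cul3 (78.2 ± 0.90 against 173 ± 7.77) were lower, with changes of −1.12 ± 0.12, −0.83 ± 0.11 and −1.15 ± 0.15 (adjusted p = 5.9e-05, 0.0011 and 0.00057). Smad4 (45.1 ± 6.28 in S211I, −1.30 ± 0.21, adjusted p = 0.0081), Znrf2 (61.2 ± 3.92, −1.15 ± 0.19, adjusted p = 0.011) and Ppp2cb (107 ± 9.35, −0.86 ± 0.16, adjusted p = 0.023) were lower too. Khdrbs3 fell from 36.0 ± 12.9 to 6.52 ± 3.75 (−2.43 ± 0.41, adjusted p = 0.023). Retreg1 fell from 16.5 ± 2.84 to 4.74 ± 1.41 (−1.80 ± 0.34, adjusted p = 0.029) and Tada2b from 46.9 ± 0.75 to 16.6 ± 3.93 (−1.49 ± 0.27, adjusted p = 0.023). Sirt1, Nfix, Brd1, Sh3tc2 and Gm7334 completed the 15. In the other direction Bex4, at 75.5 ± 8.71 against 30.6 ± 2.10 CPM, came closest (1.31 ± 0.26, adjusted p = 0.050, just over the threshold). Plvap (66.7 ± 6.28 against 31.2 ± 14.4 CPM), Mt1 (323 ± 31.4 against 207 ± 21.99), Hexa (59.9 ± 8.02 against 30.5 ± 3.96) and Helb (38.3 ± 3.52 against 21.7 ± 1.70) followed (edgeR, adjusted p = 0.103 to 0.244). Left-out libraries gave 4 to 8 genes, and DESeq2 27, voom 33 and no low-count filter 51.

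The ribosomal protein list was higher in the double mutant than in S211I MEP (50 of 51 positive, camera, adjusted p = 1.9e-11), as was oxidative phosphorylation (32 of 33, adjusted p = 6.8e-05). Both calls were lost with an estimated correlation (adjusted p = 0.64 with an estimated correlation). Rplp2 stood at 291 ± 39.7 against 229 ± 1.23 CPM (0.34 ± 0.14, edgeR, adjusted p = 0.59). The stem cell (2 of 15 positive, adjusted p = 0.00017; 2 members adjusted over the list alone), megakaryocyte (6 of 18, adjusted p = 0.00017; 6 members), monocyte (1 of 8, adjusted p = 0.014) and antigen presentation (4 of 18, adjusted p = 0.014) lists were lower (adjusted p = 0.51 to 0.64 with an estimated correlation). Cd34 stood at 3.46 ± 1.92 against 14.9 ± 0.573 CPM (−2.05 ± 0.59, adjusted p = 0.37) and Plek at 3.15 against 12.9 (−2.05 ± 0.44, adjusted p = 0.090). Cd9 stood at 5.51 ± 0.828 against 13.9 ± 4.55 CPM and Flt3 at 2.05 ± 1.28 against 6.67 ± 1.36. Ctss stood at 0.784 ± 0.876 against 3.16 ± 2.09, H2-K1 at 462 ± 16.7 against 590.4 ± 50.1 and B2m at 1036 ± 144 against 1264 ± 101. Rps10 stood at 236 ± 43.3 against 183 ± 9.999, Atp5c1 at 507.5 ± 40.2 against 421.5 ± 5.97 and Cyc1 at 441 ± 40.6 against 366 ± 4.74. The ribosomal, oxidative phosphorylation and megakaryocyte calls held without each library in turn, though a fit without an S211I library keeps 1 of them. The stem cell call was lost without S211I replicate 1 (0.15). Monocyte was lost without S211I replicates 1 or 2 or double-mutant replicate 3 (0.86, 0.15 and 0.066), turning upward without S211I replicate 1, and antigen presentation without S211I replicate 2 or double-mutant replicate 3 (0.19 and 0.095).

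Against P216L MEP (n = 3 and 3), 1 gene was higher and 11 were lower in the double mutant (edgeR, adjusted p < 0.05, 460 at an unadjusted p under 0.05). Bex4 rose from 28.8 ± 8.30 to 75.5 ± 8.71 CPM (1.41 ± 0.23, adjusted p = 0.011). Mbd2 fell from 387 ± 19.3 CPM (−0.96 ± 0.11, adjusted p = 0.00017) and Ybx3 from 1513 ± 90.0 (−0.86 ± 0.10, adjusted p = 0.00032). Cul3 fell from 159 ± 25.6 (−1.03 ± 0.14, adjusted p = 0.00079) and Qk from 136 ± 29.9 (adjusted p = 0.00085). Lower too were Znrf2, from 57.8 ± 8.42 (−1.07 ± 0.18, adjusted p = 0.011) and Ppp2cb, from 98.3 ± 9.60 (−0.74 ± 0.14, adjusted p = 0.040). Khdrbs3 (30.9 ± 14.9 to 6.52 ± 3.75), Serpina3g (13.97 ± 2.64 to 3.00 ± 1.57), Plek (13.8 ± 6.17 to 3.15 ± 1.34), Egln1 (33.3 ± 9.90 to 13.2 ± 2.09) and Spon2 (134 ± 30.3 to 77.9 ± 6.58) were the other 5 (adjusted p = 0.037, 0.017, 0.047, 0.019 and 0.047). Ccnd1 (20.2 ± 5.47 against 5.30 ± 1.69 CPM), Plvap (66.7 ± 6.28 against 34.4 ± 6.54) and Rnf128 (59.4 ± 7.50 against 32.6 ± 9.40) had the next smallest p values among the higher genes (edgeR, adjusted p = 0.062, 0.102 and 0.121). The total was 5 without P216L replicate 1, 20 without P216L replicate 3, and 5, 6 and 7 without double-mutant replicates 1, 2 and 3.

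The megakaryocyte list fell between P216L and double-mutant MEP (5 of 18 positive, camera, adjusted p = 7.3e-05, 0.26 with an estimated correlation), with Plek past the gene threshold and 3 members adjusted over the list alone. The interferon (8 of 33 positive, adjusted p = 0.0021; 1 member), B lymphoid (0 of 13, adjusted p = 0.0032) and stem cell (6 of 15, adjusted p = 0.0032) lists fell as well (adjusted p = 0.61 with an estimated correlation). So did the T and NK cell (0 of 4, adjusted p = 0.004), monocyte (1 of 8, adjusted p = 0.0049) and antigen presentation (2 of 18, adjusted p = 0.0049) lists. These 6 were lost with an estimated correlation (adjusted p = 0.26 to 0.61 with an estimated correlation). Below the threshold, Ifitm3 stood at 14.6 ± 3.47 against 29.7 ± 4.26 CPM (−1.03 ± 0.24, edgeR, adjusted p = 0.12). Cd9 stood at 5.51 ± 0.828 against 12.002 ± 1.71 CPM, Meis1 at 4.21 ± 1.75 against 9.74 ± 3.61, and Oasl2 at 1.29 ± 0.683 against 3.79 ± 1.55. Psmb8 stood at 92.1 ± 7.89 against 125 ± 2.87, H2-DMb1 at 4.20 ± 0.642 against 8.096 ± 2.86, Cd300a at 1.83 ± 0.945 against 5.46 ± 3.31 and Flt3 at 2.05 ± 1.28 against 5.35 ± 3.01. Low-count members were Dntt (0.867 against 6.45), Fcrla (0.353 against 1.32), Lck (0.774 against 2.77) and Il2rb (0.722 against 2.67). The megakaryocyte and stem cell calls held without every library. Interferon was lost without P216L replicate 1 (0.50), and B lymphoid without P216L replicate 2 (0.70). T and NK was lost without P216L replicate 2 or double-mutant replicate 2 (0.053 and 0.050), monocyte without P216L replicate 3 or double-mutant replicate 3 (0.22 and 0.057), and antigen presentation without P216L replicate 1 or double-mutant replicate 3 (0.18 and 0.11).

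Cul3, Mbd2, Ppp2cb, Qk, Ybx3 and Znrf2 were lower in double-mutant MEP than in WT, S211I and P216L MEP. Calls that were independent would share 1.1e-05 genes, and each of 20 sets simulated without effects shared 0. The simulated sets were not matched to the number of real calls. They do not show how many genes shared libraries alone would give. The same 3 double-mutant libraries enter every comparison, so part of the excess may come from them. In the test against the sum of the single changes, Qk alone passed (−1.54 ± 0.23, edgeR, adjusted p = 0.0135; 608 at an unadjusted p under 0.05). Its plain CPM was 127 ± 9.18 in WT, 136 ± 30.6 in P216L, 178 ± 6.21 in S211I and 64.4 ± 1.41 in the double mutant. Cul3 (−1.14 ± 0.21, adjusted p = 0.14), Mbd2 (−0.84 ± 0.17, adjusted p = 0.22), Ybx3 (−0.80 ± 0.16, adjusted p = 0.22), and Egln1 (−1.71 ± 0.37, adjusted p = 0.23) stayed below the threshold. So did Trnp1 (5.31 ± 1.09, adjusted p = 0.23), Asns (0.71 ± 0.17, adjusted p = 0.34), Crip2 (0.79 ± 0.20), Bex4 (1.44 ± 0.36) and Rnf128 (1.25 ± 0.32). The count was 0 to 13 when single libraries were left out, 0 with replicate number as a block, 7 with voom, 11 with DESeq2 and 32 without the low-count filter.

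**Figure D2:**
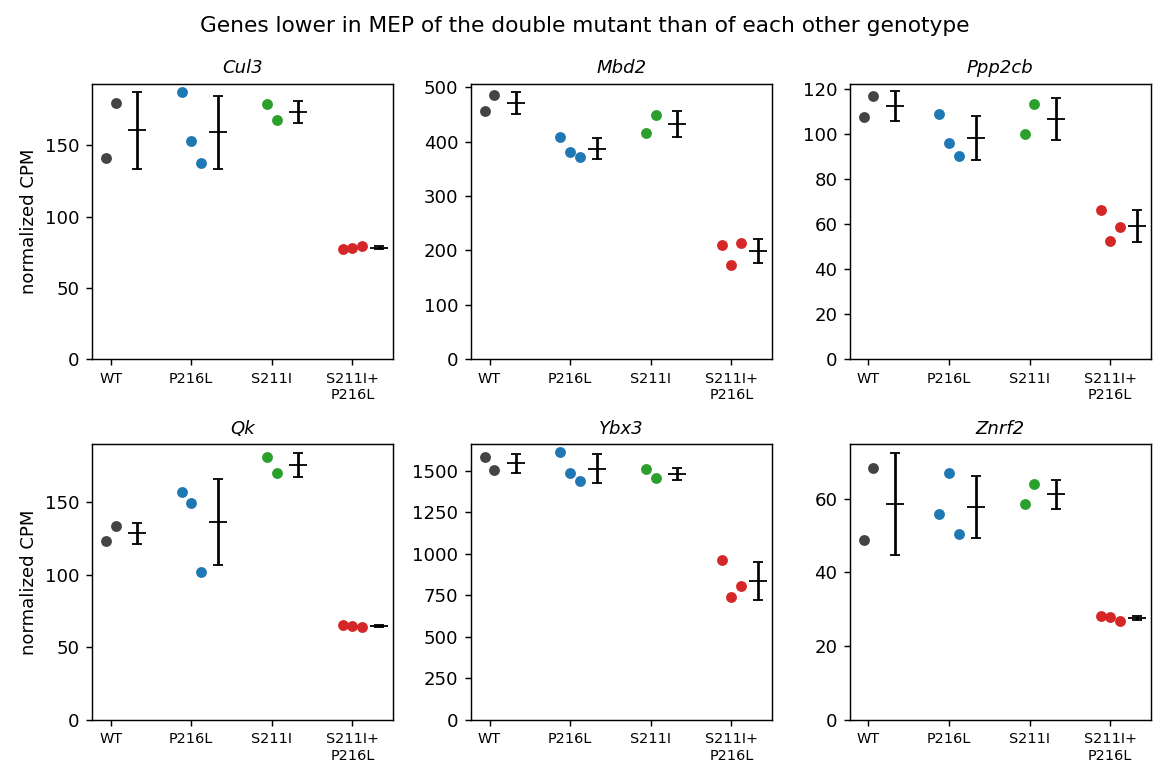
CPM of Cul3, Mbd2, Ppp2cb, Qk, Ybx3 and Znrf2 (y axes) in each MEP library by genotype (x axes). There were n = 2 WT, 3 P216L, 2 S211I and 3 double-mutant libraries. Black bars beside the points show the mean ± SD of each genotype. Mean Mbd2 was 471 CPM in WT and 199 in the double mutant.

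The effect of P216L differed between cell types for 12 genes, all with a smaller change in MEP (edgeR, adjusted p < 0.05, 1948 at an unadjusted p under 0.05). These p values come from the joint fit, whose common spread was smaller than that of HSC alone. Rrm1 averaged 24.6 ± 29.6 and 890.35 ± 481 plain CPM in WT and P216L HSC but 1239 ± 9.32 and 1153 ± 51.3 in MEP (−5.43 ± 1.02, adjusted p = 0.029). Sec24c averaged 4.40 ± 2.10, 521 ± 343, 180.2 ± 28.7 and 189.6 ± 49.1 in the same groups (−7.06 ± 1.26, adjusted p = 0.027). The SUMO-activating enzyme gene Uba2 averaged 9.16 ± 6.16, 267 ± 52.97, 522 ± 4.81 and 537 ± 49.1 (−5.19 ± 1.03, adjusted p = 0.037). For the double mutant 2 genes passed, Uba2 (374 ± 131 in HSC and 553 ± 26.9 in MEP, −5.86 ± 1.04, adjusted p = 0.041) and Mtrex (0.812 ± 1.41 in HSC WT, 309.8 ± 121 in HSC double mutant, 303 ± 16.3 and 311 ± 16.8 in MEP, adjusted p = 0.041). For S211I none passed in edgeR (0, with 1281 at an unadjusted p under 0.05; voom 15, DESeq2 474). Pcyt1a and Mrpl19 came closest for S211I (edgeR, adjusted p = 0.106 for both), and Pcyt1a, Racgap1 and Nxpe2 for the double mutant (adjusted p = 0.0545, edgeR). The 12 became 0 without any 1 of the 5 MEP libraries of those groups or without HSC WT replicate 2, 1 with replicate number as a block and 0 with voom. WT MEP already held the 12 genes, so MEP RNA in mutant HSC libraries would raise them in HSC alone. That was not tested for them.

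Across 8890 genes tested in both cell types, the change in HSC and the change in MEP had Spearman rho −0.089 for P216L, −0.122 for S211I and −0.020 for the double mutant. Among 100 regroupings of libraries, 0, 3 and 70 gave a value as far from 0. Shared calls say little here. P216L had 0 called genes in MEP, so none could be shared. For the double mutant 7 genes in HSC and 11 in MEP shared 0. However, the HSC test recovered 0 of 66 genes changed 16-fold in simulated counts. The 7 lists that passed in none of the 10 contrasts were NF-kB and TNF, glycolysis and hypoxia, unfolded protein response, cholesterol, ETS family, Etv6 co-repressor and mast cell; their smallest adjusted p values were 0.25, 0.065, 0.34, 0.30, 0.13, 0.38 and 0.24 (camera).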

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

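The tests of explanations in this part were chosen after the results were seen, except the comparison with genes matched in GC content and length and the carry-over test on 50 MEP and 57 HSC genes, whose predictions were written first; the checks of the latter came after it.

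A difference between cell types set apart 12 genes for P216L: Pcyt1a, Rrm1, Sec24c, Racgap1, Uba2, Mrpl19, Oser1, Nde1, Atad2, Hpf1, Nxpe2 and Pus7 (edgeR, adjusted p = 0.027 to 0.047). In each the rise over WT seen in HSC was absent or smaller in MEP. WT MEP already held the 12 at 82.8 (Nde1) to 1239 (Rrm1) plain CPM, against at most 24.6 in HSC WT. MEP RNA in the mutant HSC libraries would therefore raise them in HSC alone. This was not tested for these genes, and some P216L HSC means lay above MEP P216L, such as Sec24c (521 against 190). Hpf1 averaged 0.812 plain CPM in HSC WT, 258 in HSC P216L, 189 in MEP WT and 187 in MEP P216L. Pcyt1a, Racgap1, Mrpl19, Oser1, Nde1, Atad2, Nxpe2 and Pus7 had no counts in the 3 HSC WT libraries. For the double mutant 2 genes were set apart in the same way, Uba2 (9.16 ± 6.16 plain CPM in HSC WT, 374 ± 131 in the HSC double mutant) and Mtrex (0.812 ± 1.41 and 309.8 ± 121).

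A departure from the sum of the single-mutant log2 changes set apart 6 genes in HSC: Golm1, Lig3, Mcm2, Rrm1, Mtfr1 and Wdr44. The count ran from below to above 6 when single libraries were left out. The Mcm2 rise in S211I rests on the library labelled HSC S211I replicate 2 (43.1 and 1124.7 normalized CPM in the pair). Wdr44 stood at 145 ± 178 plain CPM in S211I. In plain CPM, WT, P216L, S211I and the double mutant stood at 0, 354, 375 and 141 for Golm1, 7.63, 776, 249 and 0 for Lig3 (edgeR, adjusted p = 7.8e-06), 0, 246, 369 and 316 for Mtfr1, and 0, 429, 145 and 1.94 for Wdr44 (adjusted p = 0.044, edgeR). In MEP 1 gene was set apart, Qk (−1.54 ± 0.23, adjusted p = 0.0135, edgeR), at 127 ± 9.18, 136 ± 30.6, 178 ± 6.21 and 64.4 ± 1.41 plain CPM.

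The library labelled HSC S211I replicate 2 lay near the MEP libraries (r = 0.980 with their mean). Were it an unmixed MEP library under a wrong label, genes far higher in WT HSC would sit inside the MEP range, but 44 of 57 lay above the highest MEP library, against at most 24 for any MEP library set against the others, which speaks against this. A small share of HSC in MEP material predicts a small and even share of the distance from MEP to HSC; its median was 4.66% (quartiles 2.72 and 6.38), above the highest median of an MEP library (0.603), and this fits. If the S211I genotype moved HSC toward MEP, the other HSC S211I library should lie nearer MEP than the other genotypes do, but it stood at 76.9%, far from 4.66% and inside their range of 27.9 to 181, which speaks against genotype alone but not against a smaller shift, since the WT libraries, on which the 57 genes were picked, stood at 132.6 to 181. Material mixed in the sort or in preparation and RNA carried between libraries were not told apart.

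The erythroid and S phase lists passed camera in HSC of each mutant against WT, but not with an estimated correlation (adjusted p = 0.69, 0.46 and 0.67 for P216L, S211I and the double mutant with an estimated correlation), nor for S211I without the 3 HSC libraries nearest to MEP (0.087 and 0.11). Carry-over of MEP RNA as the sole cause in P216L replicate 3 is spoken against by its own level. There 4 of 4 list sums lay above the highest MEP library. These sums cannot exclude that MEP RNA made up part of that library. Its stem cell sum was 2578 CPM, against 5495.5 to 7162.5 in HSC WT. For 6 other mutant libraries (the library labelled HSC S211I replicate 2 is left out here and of the 7 named last), carry-over predicts that 50 MEP genes rise and 57 HSC genes fall by the same share, but gain minus loss averaged −19.8 points (SE 3.70), which met the bound written in advance. That bound may be wrong for genes picked on WT, so carry-over stays open. WT libraries left out of the picking and treated as mutants gave −41.7, 4.45 and −32.5 (mean −23.2, SE 14.1). Mutants measured from the library left out gave −3.88, −11.9 and −3.92 (SE 5.42, 5.92 and 6.31), of which −11.9 alone met the bound. These 3 values use shares of summed CPM, where −19.8 and the WT values use medians over genes. The change from −19.8 may therefore come from the measure as well as from the picking. The erythroid and stem cell lists gave −47.5 to 35.9 (mean 0.38, SE 12.5), which decides nothing. Uneven depth is spoken against by thinning, where 6 of 6 list calls held; an effect of genotype predicts mutant libraries above every WT library, and 6 of 7 were for S phase (7 of 7 for erythroid), but carry-over predicts this too, so genotype stays open.

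Cul3, Mbd2, Ppp2cb, Qk, Ybx3 and Znrf2 were lower in double-mutant MEP than in the other 3 genotypes. Fewer HSC-like cells among the sorted MEP would lower genes far higher in HSC more than these 6, but against WT the median log2 fold change of 196 such genes, picked without the groups compared, was −0.044 (quartiles −0.50 and 0.32), against −1.02 for the 6. Against S211I and P216L such genes did fall (median −0.36 and −0.48, quartiles −0.91 to −0.017 and −1.08 to −0.11). The 6 lay below these medians by 0.77 and 0.52, within the interquartile ranges of 0.89 and 0.97. That comparison therefore decided nothing against S211I and P216L. The share of HSC-like cells was taken as at most 21.9 and 18.6%, from the stem cell list sums. With those shares, the 6 would have to stand 2.94- and 3.18-fold higher in HSC to fall as seen. Their median stood at most 1.27-fold higher in any of 10 HSC libraries. Under that assumption, fewer HSC-like cells are spoken against as the cause for the 6 as a set. A median does not settle this for single genes. Mean level in HSC over MEP was 1.97 for Cul3 and 1.56 for Qk, and Qk averaged 352 ± 222 plain CPM in HSC WT. The others stood at 0.53 to 1.07. Loss of one copy of a segment around Etv6 would lower its neighbours, whose median over the 20 nearest tested genes was 0.017 (quartiles −0.20 and 0.17), and a bias by GC content or length would lower matched genes, whose median over 279 was 0.0081 (quartiles −0.13 and 0.14); each value speaks against its explanation. Loss of a megakaryocyte-primed subset of the MEP was not tested and stays open beside an effect of the genotype.

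For the comparisons with 3 libraries per group, relabelling gives 10 splits, too few for a share under 0.05. The real grouping and the highest other split gave 10 and 8 genes for HSC P216L against WT, 7 and 1 for the HSC double mutant against WT, 2 and 3 for the HSC double mutant against P216L, and 12 and 1 for the MEP double mutant against P216L. Splits with as many calls as the real one, itself included, numbered 1, 1, 3 and 1.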

How the results depend on the processing

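Fits without the library labelled HSC S211I replicate 2 where a contrast does not contain it, fits without the 3 HSC libraries nearest to MEP, and thinning were chosen after the results were seen. In HSC, 16-fold changes put into simulated counts were recovered for at most 2 of 66 genes. Low depth was not told apart from the spread between libraries as the cause. In MEP, Mbd2 and Ybx3 kept their direction and their calls against WT in all 11 alternatives. Among results beyond the counts of calls, 502 comparisons with an alternative kept their call and direction, 283 lost the call, 33 moved in value and 3 reversed. Single lists are counted apart from these: 5 times a list that passed turned in direction, the stem cell list in S211I HSC in 2 fits, antigen presentation in P216L and in S211I MEP, and monocyte between the double mutant and S211I MEP. Fits without the low-count filter tested more genes, fits of only the groups compared used fewer libraries, and thinning left fewer genes and counts; the cause of the other changes was not tested. Relative log expression size factors are written RLE.

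For HSC P216L vs WT the 10 genes became 18 with RLE (15 higher, 3 lower), 0 without the low-count filter, 60 with voom, 270 with DESeq2, 0 with only the groups compared, 2 without the 3 libraries nearest to MEP, 2 after thinning, and 4 to 25 with single libraries left out. For HSC S211I vs WT the 8 became 5 with RLE, 0 without the filter, 15 with the replicate block, 623 with voom, 61 with DESeq2, 0 with only the groups compared, 1 without the 3 libraries, 2 after thinning and 2 to 22 with single libraries left out. For HSC S211I_P216L vs WT the 7 became 0 without the filter, 11 with the block, 221 with voom, 128 with DESeq2, 0 with only the groups compared, 2 without the 3 libraries, 2 after thinning and 1 to 24 with single libraries left out; RLE gave 5 higher and 1 lower.

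For HSC S211I_P216L vs S211I the 1 gene became 0 without the filter, with the Y-linked covariate, with only the groups compared and after thinning, 115 with voom, 8 with DESeq2, 2 without the 3 libraries and 0 to 2 with single libraries left out. For HSC S211I_P216L vs P216L the 2 became 1 with RLE and with voom, 0 with the block, the Y-linked covariate, only the groups compared and thinning, 41 with DESeq2, 4 without the 3 libraries and 0 to 4 with single libraries left out. For HSC non-additivity the 6 became 10 with RLE (3 higher, 7 lower), 1 without the filter, 10 with the block, 84 with voom, 79 with DESeq2, 3 after thinning and 1 to 16 with single libraries left out.

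For MEP P216L vs WT the 0 genes became 10 without the filter, 2 with DESeq2 and 0 to 7 with single libraries left out; MEP S211I vs WT stayed at 0. For MEP S211I_P216L vs WT the 11 became 40 without the filter, 39 with voom, 25 with DESeq2, 21 with only the groups compared and 3 to 11 with single libraries left out. For MEP S211I_P216L vs S211I the 15 became 51, 33, 27 and 28 in the same order, and 4 to 8; for MEP S211I_P216L vs P216L the 12 became 47 without the filter, 34 with voom, 26 with DESeq2 and 5 to 20. For MEP non-additivity the 1 became 32 without the filter, 0 with the block, 7 with voom, 11 with DESeq2 and 0 to 13 with single libraries left out.

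For P216L effect MEP vs HSC the 12 became 1 with the block, 0 with voom, 956 with DESeq2 and 0 to 78 with single libraries left out; for S211I effect MEP vs HSC the 0 became 2 without the filter, 15 with voom, 474 with DESeq2 and 0 to 53. For S211I_P216L effect MEP vs HSC the 2 became 0 with RLE, the block and voom, 1 without the filter, 10 with the Y-linked covariate, 670 with DESeq2 and 0 to 72. For WT MEP vs WT HSC the 493 became 266 with RLE (194 higher, 72 lower), 750 with the Y-linked covariate, 1865 with voom, 2211 with DESeq2, 0 with only the groups compared and 135 to 716 with single libraries left out.

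Of the gene lists, 62 calls became 0 with an estimated correlation and 0 with fry, 76 with the block and 64 with RLE. The 4 genes shared by HSC P216L and the HSC double mutant became 0 without the filter, 7 with the block and 1 to 22 with single libraries left out. The 0 shared by MEP P216L and the MEP double mutant became 2 without the filter and 0 to 2 with single libraries left out. The correlation of HSC and MEP changes moved for P216L from −0.089 to −0.031 without the filter (−0.110 to −0.034 with single libraries left out), for S211I from −0.122 to −0.028 (−0.129 to −0.064), and for the double mutant ran from −0.033 to 0.0046; a shift over the spread of the regroupings counted as moved, a bound set after the values were seen. The log2 fold change of Etv6 in MEP P216L reversed from 0.15 to −0.067 with voom, −0.0015 without P216L replicate 2 and −0.062 without WT replicate 1, and reached 0.43 without WT replicate 3.

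Equal replicate numbers were compared across genotypes: in HSC 15 pairs had residual correlations of −0.067 to 0.25, with 1 over 0.1 and 4 of 11 libraries closest to one of their own number, and in MEP 12 pairs had −0.092 to 0.034, with 0 over 0.1 and 1 of 10. The numbers were therefore treated as labels only, and the block results above are alternatives.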

Other observations

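The neighbour comparison below was made after the results were seen, and none of these observations came from a test written in advance.

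Ybx3, lower in double-mutant MEP, lies 2 tested genes from Etv6 on the chromosome of Etv6, with Smim10l1 between them. Smim10l1 had a log2 fold change of 0.12 against WT, and the 20 tested genes nearest to Etv6 had a median of 0.017. Of the 6 genes lower than in all other genotypes, 2 lie on that chromosome, which holds 4.83% of 10515 tested genes. Over all genotypes, without the library labelled HSC S211I replicate 2, the mean level of the 6 genes in HSC over MEP ranged from 0.53 to 1.97, where the genes chosen as far higher in HSC had a median ratio of 42.7.

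Ribosomal protein genes made up 22736 and 23723 CPM in the S211I MEP libraries, 25001 to 28793 in WT MEP, 24090 to 30510 in P216L MEP and 24474 to 31074 in double-mutant MEP. D3Ertd751e and Spice1 stood among the smallest p values in both single mutants in MEP (edgeR, adjusted p = 0.31 and 0.71 in P216L and 0.94 for both in S211I). The 2 comparisons share the WT libraries, in which D3Ertd751e averaged 4.69 ± 2.62 CPM.

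Endothelial and stromal genes summed to 17492 CPM in HSC P216L replicate 1, 8173.6 in HSC double-mutant replicate 3, 2461 in HSC S211I replicate 1 and 1845 in HSC WT replicate 2, against 32.9 to 595 in the other HSC libraries. Summed S phase CPM ran from 1521 to 3982 in HSC WT, from 3175 to 14893 in the HSC mutants and from 10706 to 11878 in MEP.

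Work outside the scripts that gave no reported result included a contrast of double-mutant MEP against the mean of the other genotypes, the direction of its genes in HSC, a scan of 3′ untranslated regions for short sequences with several scorings, in which no known site was recognised, and the chromosome positions of the leading genes, from which the observation on Ybx3 came.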
